A study of Mus musculus with 2 samples.

How the data were processed

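Leukocytes from left ventricles of mice with transplanted marrow were profiled after TAC as 2 libraries, 1 for control and 1 for LOY marrow, each from 3 mice pooled after sorting for viable CD45+ RFP+ cells, with about 8000 cells per library used, per the labels' protocols. Libraries were made with a 10x Genomics 3' kit, so transcripts are counted near their 3' end and once per UMI. Per the submitters' processing notes, Cell Ranger 5.0.0 and the build mm10 were used. The deposited values are raw UMI counts per gene and barcode, with no normalization. The feature list had 32285 genes and an RFP sequence. The annotation release and the filter on barcodes were not given in the sources used here, and the lowest barcode total was 500 UMIs. Gene positions were taken from GENCODE M21, on the same build.

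Cells with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept (Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Doublets were scored with scrublet, run through scanpy, within each library. Its automatic threshold marked 1.26% of control barcodes (88) and 0% in the LOY library, so there the highest scores, at 0.8% per 1000 barcodes, were removed (235, 4.34%), by a rule fixed in advance. The libraries were thus treated unequally, and keeping all doublets was an alternative. Counts were scaled to 10000 per cell and log-transformed. Both libraries were clustered together on 2000 variable genes, without Y-linked genes, Xist, mitochondrial, ribosomal-protein, haemoglobin, immunoglobulin and T cell receptor genes. The steps used 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9, seed 0), with no batch correction. The 24 clusters were named from markers of 18 cell types fixed before the data were examined, whereas the scoring was not fixed in advance. A cluster took the type with the highest share of its markers seen in at least 25% of its cells. It stayed numbered when fewer than 3 markers were found, when its top 10 genes by fold held more markers of another type, or when its cells had a median under 1/3 of their library's UMIs with no marker of the type among those genes. Markers at about the same share in every cluster were not counted among the top genes. The names are rebuilt from markers, so shares can differ from the study's own.

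UMIs were summed per class and library and divided by the class total (CPM). The ratio was log2((LOY CPM + 10)/(control CPM + 10)), which understates differences of low genes, and folds given with an interval are plain ratios of CPM. Classes with at least 100 cells in each library were compared. With 1 library per group there was no test, p-value or count of changed genes. Sums have exact Poisson intervals, ratios of sums exact conditional intervals and shares exact Clopper-Pearson intervals, all at 95%, and a count of 0 is given with the limit of 3 counts. For shares of cells with a Y-linked UMI, each cell was thinned without replacement to 1000 UMIs, the 10th percentile of UMIs per kept LOY cell (1231) rounded down to a multiple of 500, and shallower cells were left out. The estimated share without Y transcripts is 100% less the LOY share as a percent of the control share. Its interval came from 10000 draws of both shares from beta (Jeffreys) distributions, in place of the plain binomial resampling first planned, so that a share of 0 has an interval.

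Gene lists (27) were fixed before the data were examined. They cover the Y-linked genes, their X-linked partners, profibrotic and TGF-β genes, inflammation, interferon, antigen presentation, macrophage origin, efferocytosis, lysosome, metabolism, cell cycle, p53, dissociation stress, lymphocyte and granulocyte states and transcripts of other cell types. Of the listed symbols 3 were not used, Ctgf and Mx1, which are not among the feature symbols, and Aldoa, whose symbol belongs to 2 features. A member counted as measured at 10 CPM or more in either library. Each list has its median log2 ratio, a counting interval from 1000 Poisson draws, its percentile among 10000 random lists matched on mean expression in 20 bins, and the members over 1.5-fold on the scale with the added 10 CPM. Some genes stand in more than 1 list. Genes named in the text are the Y-linked genes, Tgfb1, the 10 highest and 10 lowest ratios in macrophage-like cells and the 5 highest and 5 lowest in each other class. These had at least 50 CPM in the higher library and 50 UMIs over both, without the gene families left out of clustering and unnamed gene models. The 2 highest and 2 lowest members of lists, and the 5 highest and 5 lowest genes of the split by Y-linked UMI, are also named. Outside this rule stand Xist, genes that lead clusters, the gene models Gm47283 and Gm21860 on chromosome Y, and genes apart in the same direction in all 5 classes (the 5 with the largest median ratio each way, those that share sequence with other genes, and B2m). All these but Xist were chosen after their values were seen. List members in classes other than macrophage-like cells are given in part, and 1 list member in macrophage-like cells is not reported here.

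On simulated counts for all kept cells, 200 of 2631 genes were changed by known amounts. Of the 50 genes each raised 2-fold, raised 4-fold, and lowered as much, 100% passed 1.5-fold in the right direction, and 0% of the 2431 unchanged genes did. All 20 genes named by the rule in this simulation were changed ones. The simulated counts held counting error only, at the depth of all kept cells. The simulation therefore checks neither differences in preparation between libraries nor folds in small classes, such as the 120237 LOY UMIs of neutrophil-like cells. Of 40 random lists of unchanged genes, 39 lay within the central 95% of matched lists. For the estimated share without Y transcripts, a first single simulation at a true share of 50% gave an interval that missed it. It was replaced by 200 repeats, in which 94% of the intervals held a true share of 50% and 97% one of 90%. Alternatives changed the UMI minimum (1000), the mitochondrial limit (5%), doublet removal, clustering resolution (0.5 and 2), separate clustering of each library, Y-linked genes in clustering, and the genes behind CPM. Others were scaling by TMM (edgeR 4.0.16, R 4.3.3), equal weight per cell, pseudocounts of 1 and 50 CPM, a limit of 100 CPM for named genes, macrophage-like and monocyte-like cells together, the thinning depth (500 and 2000), and each Y-linked gene alone. Added after the data were seen were the Lyve1 cluster alone, thinned cells and the class without cycling clusters.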

Results

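The study compared blood-derived cells of the heart in mice whose transplanted bone marrow was either control or LOY (loss of the Y chromosome). All mice underwent transverse aortic constriction (TAC), a surgical narrowing of the aorta that loads the left ventricle, and the title of the study sets the comparison in cardiac fibrosis. Viable CD45+ RFP+ cells, leukocytes that derive from the transplanted marrow by the labels, were sorted from left ventricles and profiled by droplet single-cell RNA sequencing. Each group was 1 library from 3 mice pooled after the sort. No difference given here has a replicate check, no test was run, and all intervals (95%) cover counting error only. The control library held 7276 barcodes with 42640861 UMIs (unique molecular identifiers, each a counted transcript), a median of 5109.5 per barcode. The LOY library held 5475 barcodes with 18710715 UMIs, a median of 3026. After filtering, 6904 control and 5180 LOY cells remained. The added RFP sequence had 0 UMIs in both libraries, a limit for UMIs assigned to that sequence of 0.0704 CPM (counts scaled to the same total in each library or class) in the control and 0.160 CPM in the LOY library. Whether the sequence holds the 3' end at which transcripts are counted was not given in the sources used here, so no level of RFP expression is read from it. Paired values below give the control first and the LOY library next.

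The labels were checked first with the Y-linked genes Ddx3y (an RNA helicase), Eif2s3y (a translation initiation factor subunit), Kdm5d (a histone demethylase) and Uty. Together they had 5133 UMIs in the control library, 124 CPM (exact Poisson interval 121 to 128), and 245 UMIs in the LOY library, 14.0 CPM (12.3 to 15.9). The LOY level was 11.3% of the control level (9.88% to 12.8%), and each of the 4 genes was lower. Ddx3y (ENSMUSG00000069045, mm10 chromosome Y, 1260771 to 1286629) had 50.8 CPM in the control and 6.75 CPM in the LOY library. Eif2s3y (ENSMUSG00000069049, chromosome Y, 1010543 to 1028847) had 47.3 and 4.29 CPM. Kdm5d (ENSMUSG00000056673, chromosome Y, 897788 to 956786) had 13.5 and 1.43 CPM, and Uty (ENSMUSG00000068457, chromosome Y, 1096861 to 1245759) had 12.7 and 1.54 CPM. Xist, the RNA of the inactive X chromosome, had 1 UMI in the control and 0 in the LOY cells kept, which allows up to 0.172 CPM in the latter. The X-linked partners were closer between libraries. Ddx3x was at 81.1% of the control level (77.0% to 85.5%), Eif2s3x at 69.6% (61.6% to 78.4%), Kdm6a at 96.3% (84.7% to 109%) and Kdm5c at 116% (102% to 132%).

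**Figure D1:**
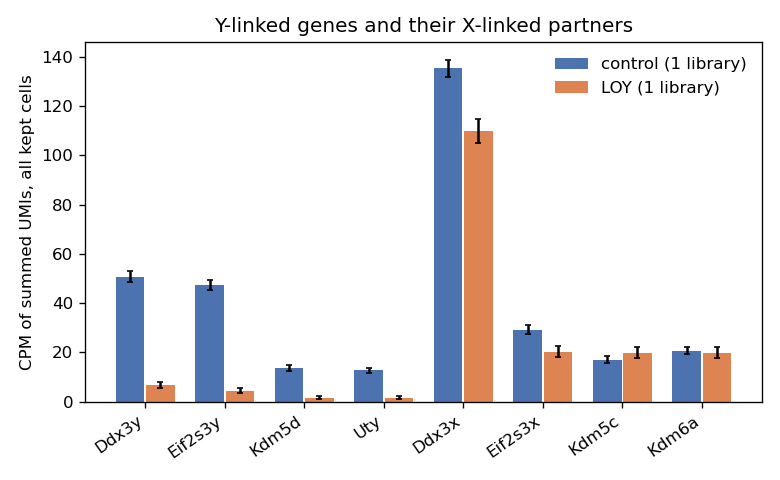
CPM of the 4 Y-linked genes and their 4 X-linked partners over all kept cells, with 1 bar per library and exact Poisson 95% intervals. The Y-linked genes stood at 6.75 CPM or less in the LOY library, against 12.7 to 50.8 CPM in the control library.

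The Y-linked level was lower in the LOY library in macrophage-like, monocyte-like, lymphoid and neutrophil-like cells. In macrophage-like cells the Y-linked sum was 114 CPM in the control (110.3 to 118) and 14.5 CPM in the LOY library (12.5 to 16.6). Monocyte-like cells had 169 and 16.1 CPM, and B cell-like cells 180.2 and 18.4 CPM. T cell-like cells had 181 UMIs in the control and 1 in the LOY library, 3.16% of the control level (0.0796% to 17.8%), and neutrophil-like cells 181 and 1, 3.58% (0.0901% to 20.2%). NK cell-like cells had 175 CPM in the control and 0 UMIs in the LOY library, which allows up to 30.6 CPM. With every cell thinned to 1000 UMIs, 12.0% of control cells (820 of 6849, exact Clopper-Pearson interval 11.2% to 12.8%) and 1.32% of LOY cells (63 of 4790, 1.01% to 1.68%) had a Y-linked UMI. The unthinned shares were 46.6% and 3.76%. Thinning left out 55 control and 390 LOY cells that were shallower. With the control share as the rate of detection at this depth, the estimated share of LOY-library cells without Y transcripts was 89.0% (86.0% to 91.6%). It was 87.4% in macrophage-like cells (83.3% to 90.7%), 92.5% in monocyte-like cells (79.4% to 97.9%) and 90.7% in B cell-like cells (56.9% to 99.0%). The B cell-like value rests on 62 of 237 LOY cells, 1 of them with a Y-linked UMI. Lower estimates with wide intervals came from the numbered cluster 9 (64.3%, -5.95% to 87.3%) and conventional dendritic cell-like cells (64.3%, -41.5% to 93.3%). They rest on 5 of 71 control and 9 of 358 LOY cells, and on 7 of 70 and 2 of 56. Without thinning, the Y-linked sums there were 14.4% (7.09% to 27.1%) and 12.3% (3.92% to 29.4%) of the control level, near the 12.7% of macrophage-like cells. None of the 83 T cell-like, 37 NK cell-like or 27 neutrophil-like LOY cells thinned to 1000 UMIs had a Y-linked UMI. This allows shares of cells with one of up to 3.61%, 8.11% and 11.1%. The few fibroblast-like LOY cells (10) had 4 Y-linked UMIs, 41.3% of the control level (10.4% to 121%).

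Macrophage-like cells made up most of both libraries. They were 67.8% of control cells (4684 cells, Clopper-Pearson interval 66.7% to 68.9%) and 72.9% of LOY cells (3777 cells, 71.7% to 74.1%). Lymphoid and neutrophil-like cells had lower shares in the LOY library. B cell-like cells were 11.8% of the control (11.02% to 12.6%) and 4.58% of the LOY library (4.02% to 5.18%). T cell-like cells were 3.88% and 1.87%, NK cell-like cells 2.78% and 0.907%, and neutrophil-like cells 4.32% and 2.36%. Monocyte-like cells were 3.61% and 4.50%, and conventional dendritic cell-like cells 1.01% and 1.10%. Platelet-like, fibroblast-like, endothelial cell-like and plasmacytoid dendritic cell-like cells had at most 19 cells in a library. The sort, the minimum of 500 UMIs and the depth gap can set these shares. B cell-like cells had a median of 2049 UMIs in the control and 854 in the LOY library, where 73.8% lay under 1000 UMIs, and neutrophil-like cells 2039.5 and 819, with 77.9% of the LOY cells under 1000. At a minimum of 1000 UMIs the LOY shares were 1.29% for B cell-like and 0.647% for neutrophil-like cells, and at no more than 5% mitochondrial UMIs the B cell-like shares were 5.24% in the control and 3.64% in the LOY library. With each library clustered on its own no LOY cluster was named NK cell-like, and the LOY T cell-like share was 2.84%. The macrophage-like share ran from 48.6% to 71.3% in the control and from 54.1% to 79.96% in the LOY library over the alternatives, and the LOY monocyte-like share reached 10.2%, so no order between the libraries is read from either.

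**Figure D2:**
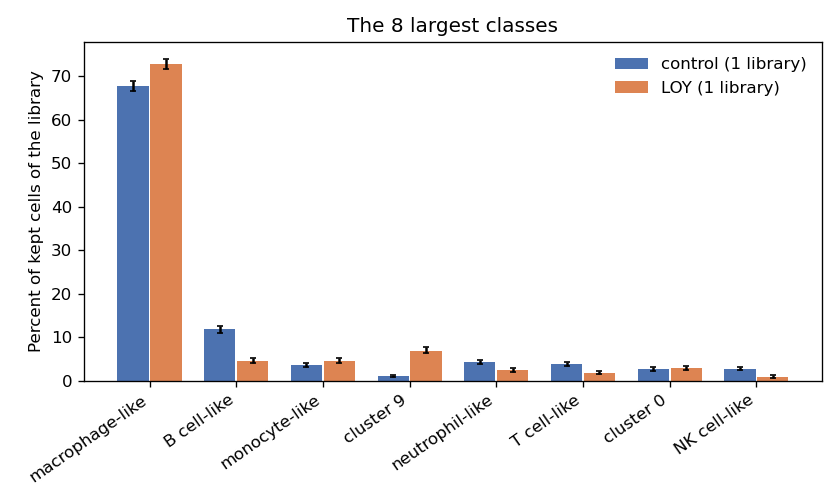
Percent of each library's kept cells in the 8 largest classes, with 1 bar per library and exact Clopper-Pearson 95% intervals. B cell-like cells stood at 11.8% in the control and 4.58% in the LOY library, and macrophage-like cells were the largest class in both.

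Clusters 0, 9 and 21 met no name and stayed numbered. By share of markers each was closest to macrophages, but their leading genes held more markers of another type. That type was monocyte for clusters 0 and 9, whose cells are not in the monocyte-like class, and cardiomyocyte for cluster 21. Clusters 0, 9 and 21 held 2.64%, 1.04% and 0.377% of control cells and 2.93%, 6.93% and 1.29% of LOY cells. Cluster 0 was led by Cd209a and Ccl17, cluster 9 by Ly6c2 and AA467197, and cluster 21 by the cardiac muscle genes Myl7 and Tnnt2. Different clusters held most of the macrophage-like cells of each library. In the control these were led by H2-Eb1, Lyve1, Rgs1, Slc40a1 and Cxcl9, and in the LOY library by Tmem119, Gpnmb, Ly6a, Lyve1 and Cenpf. Of the 11 macrophage-like clusters, 5 had over 90% of their cells from 1 library. A cluster of mostly 1 library may be that library and not a cell type, so the class values below compare mixtures of unlike clusters. The Lyve1 cluster, with 911 control and 422 LOY cells, was compared on its own, a choice made after the data were seen.

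In macrophage-like cells, from the H2-Eb1, Lyve1, Rgs1, Slc40a1 and Cxcl9 clusters in the control and mostly the Tmem119, Gpnmb and Ly6a clusters in the LOY library, Spp1 (osteopontin, a secreted matrix protein) was among the genes with the highest ratio. It had 25.1 CPM in the control and 356 CPM in the LOY library, 14.2-fold (13.2 to 15.3). The lysosomal protease Ctsd had 627 and 2831 CPM, 4.51-fold (4.44 to 4.59). Apoc2, an apolipoprotein that activates lipoprotein lipase, was 8.69-fold higher, Ly6c2, a surface marker of recruited monocytes, 19.0-fold, Syngr1 14.8-fold, Tmem119, best known from microglia, 7.45-fold, and Olfml3 5.39-fold. The histone genes Hist1h3e, Hist1h2ab and Hist2h2ac were 8.80-fold, 7.76-fold and 5.62-fold higher. At the other end stood the MHC class II genes H2-Eb1 (9479 CPM in the control and 1525 CPM in the LOY library), H2-Aa (9250.1 and 1496 CPM) and H2-Ab1 (8161 and 1731 CPM). With them were immediate early and stress genes. Btg2 had 1121 and 154 CPM, Klf2 1099 and 187 CPM, Dusp1 1254 and 311 CPM, Zfp36 747 and 156 CPM and the heat shock gene Hspa1a 878 and 202 CPM. The transcription factor gene Cebpb had 653 and 98.6 CPM, and Bcl2a1d, of a family of near-identical genes, 50.5 and 5.26 CPM. Btg2, Cebpb, Klf2 and Zfp36 were also lower by at least 1.5-fold in the other 4 classes compared. Over 7843 measured genes the median log2((LOY CPM + 10)/(control CPM + 10)), called the log2 ratio below, was -0.019. Spp1, Ctsd, Apoc2, Syngr1, Tmem119 and Olfml3 are also among the 10 leading genes of clusters with over 90% of their cells from the LOY library, the MHC class II genes lead the H2-Eb1 cluster of mostly control cells, and Hist1h2ab and Hist2h2ac a histone cluster. In the Lyve1 cluster alone 7 of these 20 genes ranked again among the 10 highest or 10 lowest, and there the log2 ratio of Spp1 was 0.39 against 3.38 in the whole class, that of Ctsd 1.73 and that of H2-Eb1 -3.07.

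Tgfb1 (ENSMUSG00000002603, mm10 chromosome 7, 25687002 to 25705077), a TGF-β ligand and a driver of fibroblast activation, had 201 CPM in control and 264 CPM in LOY macrophage-like cells, 1.31-fold (1.26 to 1.37). It was also higher in monocyte-like cells, with 289 and 495 CPM, 1.71-fold (1.47 to 1.98), and in cluster 0, with 192 and 265 CPM, 1.38-fold (1.13 to 1.68). In neutrophil-like cells (123 and 175 CPM) and B cell-like cells (191 and 230.5 CPM) the interval of the ratio held 1. The list of TGF-β ligands, activation and receptors had a median log2 ratio of 0.10 over 12 measured members (counting interval 0.035 to 0.17), at the percentile 79.2 of random lists matched on expression. In it 2 members were over 1.5-fold higher and 10 within 1.5-fold. Thbs1, which activates latent TGF-β, was highest at 3.57 and 23.7 CPM, followed by the integrin Itgav at 34.4 and 58.3 CPM, and the receptors Tgfbr2 (232 and 167 CPM) and Acvrl1 (94.2 and 77.4 CPM) were lowest. The ligand list had medians of -0.15 in monocyte-like cells (-0.36 to 0.070), where Thbs1 was lower at 436 and 220.3 CPM, -0.33 in cluster 0 (-0.67 to -0.18), -0.070 in neutrophil-like cells (0.22 with doublets kept) and -0.028 in B cell-like cells (0.60 with separate clustering). With no more than 5% mitochondrial UMIs the monocyte-like median was 0.00060. TGF-β signalling and target genes had a median of 0.0029 over 18 members (-0.067 to 0.037), with 1 over 1.5-fold higher and 3 lower, and -0.072 with thinned cells. In the other 4 classes the median of this list was below 0. It was -0.49 in B cell-like cells (-0.96 to -0.15) and -0.35 in cluster 0 (-0.69 to -0.16). Monocyte-like cells had -0.31 (-0.57 to -0.053) and neutrophil-like cells -0.29 (-0.60 to -0.091). In that order these lay at the percentiles 2.7, 5.98, 4.9 and 19.1 of random lists. The medians of all measured genes in these classes were also below 0, at -0.15, -0.089, -0.088 and -0.18. The B cell-like median was -0.051 with separate clustering, and that of cluster 0 -0.15 with a pseudocount of 50 CPM. Pmepa1, a TGF-β target, had 60.7 and 250.1 CPM and Smad7 17.3 and 26.4 CPM, whereas Id3 (112 and 22.3 CPM) and Junb (1367 and 546 CPM) were lower. In the Lyve1 cluster the log2 ratio was 0.48 for Tgfb1, 0.085 for Thbs1 and 1.19 for Pmepa1, and the median of the ligand list was 0.016, against 0.23 in the whole class with CPM free of mitochondrial and ribosomal-protein genes.

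Profibrotic macrophage genes were higher on balance. Of 24 measured members, 12 were over 1.5-fold higher and 5 over 1.5-fold lower, with a median log2 ratio of 0.39 (0.35 to 0.45) at the percentile 100 of random lists. The members Spp1, Gpnmb, Fabp5, Ctsd and Trem2 are also among the 10 leading genes of the Gpnmb cluster, with 12 control and 757 LOY cells. Random lists were matched on expression only, so the percentile does not allow for members that rise together in 1 cluster. Spp1 and Ctsd led the list, and the tetraspanin Cd9 (193 and 86.9 CPM) and the alternative activation marker Retnla (583 and 148 CPM) were lowest. The median was 0.19 when monocyte-like cells were added to the class, 0.21 with a pseudocount of 50 CPM and 0.33 in the Lyve1 cluster. Recruited monocyte genes had a median of 0.44 over 11 members, 5 of them over 1.5-fold higher. The chitinase-like gene Chil3 was at 0.90 and 33.9 CPM beside Ly6c2, and Ccr2 (319 and 226 CPM) and Cd44 (104 and 70.2 CPM) were lowest. This median was 0.059 in the Lyve1 cluster, and in monocyte-like cells it was 0.025 (-0.11 to 0.18). Resident macrophage genes had a median of -0.30 over 17 members, with 6 over 1.5-fold lower. Mgl2 (460.3 and 150.3 CPM) and Ccl24 (117 and 38.9 CPM) were lowest, and Fcna (86.6 and 133 CPM) and Cbr2 (489 and 683 CPM) highest. The resident median was 0.10 in the Lyve1 cluster. Members of this list, among them Lyve1, Folr2 and Cbr2, are leading genes of that cluster, so the value does not check the list.

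Antigen presentation genes were lower in macrophage-like cells. The MHC class II list had a median log2 ratio of -1.44 over 9 members (-1.54 to -1.38), 7 of them over 1.5-fold lower. Its highest members were the protease Ctss, with 1746 and 2094 CPM in the class but a log2 ratio of -0.18 in the Lyve1 cluster, and H2-Ob, with 10.9 and 3.96 CPM and a log2 ratio of -0.58. The MHC class I list had a median of -0.86 over 15 members, 8 of them over 1.5-fold lower. H2-T23 (308 and 96.9 CPM) and the peptide transporter Tap2 (56.8 and 18.7 CPM) were lowest, while Psmb10 (213 and 277 CPM) and Tapbp (157 and 176 CPM) were highest. This list was lower in the other 4 classes compared as well, with medians of -0.68 in monocyte-like cells, -0.80 in neutrophil-like cells (-0.70 with members at 0 UMIs set to 3 counts, -0.38 with doublets kept and -0.50 with separate clustering), -0.61 in cluster 0 and -0.39 in B cell-like cells, except that the monocyte-like median was 0.022 at a minimum of 1000 UMIs. That median was also -0.15 at no more than 5% mitochondrial UMIs, -0.25 at resolution 0.5, -0.29 with doublets kept, -0.31 with a pseudocount of 50 CPM and -1.08 with separate clustering. H2-T23, H2-D1 and B2m were at least 1.5-fold lower in all 5 classes. The dissociation and stress list, whose immediate early genes respond to tissue digestion, had a median of -1.28 over 25 members (-1.31 to -1.22), with 19 over 1.5-fold lower. The chaperones Hspa8 (1732 and 1857 CPM) and Hsp90ab1 (1866 and 1984 CPM) were its highest members. Its median was -0.75 in the Lyve1 cluster and -0.84 at a minimum of 1000 UMIs. Inflammatory cytokines and chemokines had a median of -0.37 over 24 members, 11 of them over 1.5-fold lower. Il1b was at 492 and 149.8 CPM, and the T cell chemokine Ccl5 at 50.5 and 147 CPM and Cxcl16 at 478 and 691 CPM were highest. Within the Lyve1 cluster this list had a median of 0.13. Its median was -0.67 in cluster 0, -0.18 in neutrophil-like cells (-0.028 with members at 0 UMIs set to 3 counts), 0.051 in B cell-like cells (-0.53 with doublets kept) and 0.28 in monocyte-like cells (-0.83 with separate clustering). The p53 and DNA damage list had a median of -0.078 over 16 members. Its lowest members were Btg2 and Pmaip1 (31.6 and 12.2 CPM), and its highest Phlda3 (23.5 and 35.01 CPM) and Sesn2 (9.07 and 15.3 CPM). The log2 ratio of Pmaip1 was 0.010 in the Lyve1 cluster. The p53 medians of the other classes lay between -0.38 in neutrophil-like cells and -0.21 in cluster 0.

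Proliferation and metabolism lists were higher. Cell cycle genes had a median log2 ratio of 0.62 over 24 members (0.53 to 0.67), with 13 over 1.5-fold higher and 0 lower. The tubulin regulator Stmn1 had 167 and 464 CPM and the topoisomerase Top2a 55.3 and 141 CPM, and Pcna (110.0 and 84.5 CPM) and Cenpa (41.7 and 38.9 CPM) were lowest. Without the clusters led by cell cycle or histone genes the median was 0.33, in the Lyve1 cluster 0.39 and with a pseudocount of 50 CPM 0.33. Oxidative phosphorylation genes had a median of 0.49 over 27 members, 11 of them over 1.5-fold higher. Uqcrq (172 and 382 CPM) and Ndufa2 (175 and 384 CPM) were highest, and Ndufa4 (243 and 171 CPM) and Sdhc (68.4 and 48.5 CPM) lowest. The median was also above 0 in cluster 0 (0.39), B cell-like cells (0.28), monocyte-like cells (0.15) and neutrophil-like cells (0.051, interval -0.18 to 0.28, and 0.30 with doublets kept). Uqcrq, Cox4i1 and Atp5e belong to 19 genes at least 1.5-fold higher in all 5 classes compared, of which 7 stayed so once the trend with GC content was removed. Hypoxia and glycolysis genes had a median of 0.40 over 18 members, with Pkm at 237 and 615 CPM and Gapdh at 779.6 and 1499.9 CPM at the top. Pfkfb4 (51.7 and 34.5 CPM) and Eno1 (89.3 and 36.6 CPM), a gene with near-identical copies and lower in all 5 classes, were lowest. The hypoxia list had a median of 0.22 in the Lyve1 cluster, 0.20 in B cell-like cells (-0.10 to 0.39) and 0.14 in cluster 0. In neutrophil-like cells it was 0.086 (-0.17 to 0.34), but -0.011 with doublets kept and -0.028 with separate clustering. With separate clustering the B cell-like median was 0.43. Lysosome and lipid handling genes had a median of 0.39 over 22 members, 7 of them over 1.5-fold higher. Beside Ctsd, Gpnmb, a glycoprotein of lipid-laden macrophages, had 3.38 and 40.8 CPM, while Lpl (361 and 134 CPM) and Cd36 (200.2 and 86.4 CPM) were lowest. The lysosome list had a median of 0.082 in monocyte-like cells and, of the other sign, -0.68 in cluster 0. Efferocytosis and complement genes had a median of -0.11 over 16 members, 6 of them over 1.5-fold lower, 9 within 1.5-fold and 1 higher. Stab1 at 257 and 547 CPM and Mertk at 45.3 and 68.9 CPM were highest. Type I interferon response genes had a median of 0.29 over 24 members, 20 of which stayed within 1.5-fold, and a median of 0.53 in the Lyve1 cluster and 0.58 with each library clustered on its own. The interferon median was 0.29 in cluster 0, but -0.23 in neutrophil-like cells (-0.47 to -0.0043), with 5 members over 1.5-fold lower and 2 higher, and there it was 0.27 with doublets kept and 0.46 with separate clustering. Ifi27l2a, higher in all 5 classes, was at 2129 and 3904 CPM, Irf7 at 223 and 400.3 CPM, Ifi204 at 289.8 and 230.5 CPM and Oas1a at 29.9 and 13.6 CPM. The X-linked partner list had a median of -0.10 over 4 members in this class and 0.065 in the Lyve1 cluster. In the other classes compared the median lay between -0.58 and -0.34, at percentiles from 7.02 to 28.1 of random lists. Its interval held 0 in monocyte-like (-0.55 to 0.027) and neutrophil-like cells (-1.19 to 0.24).

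**Figure D3:**
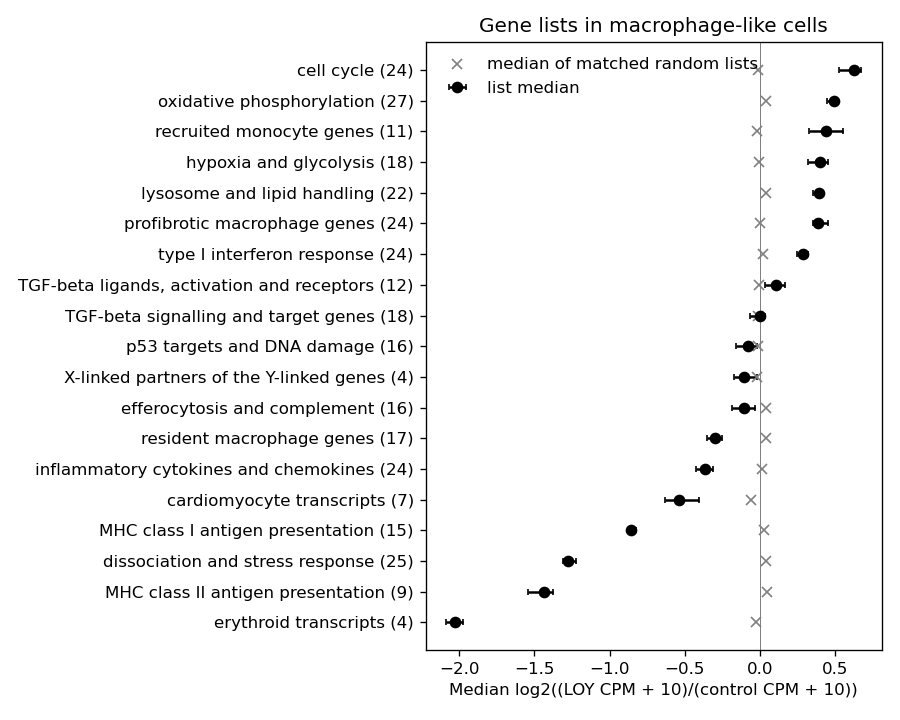
Median log2((LOY CPM + 10)/(control CPM + 10)) of each gene list in macrophage-like cells, with the number of measured members in brackets, Poisson resampling 95% intervals as bars and the median of matched random lists as crosses. Cell cycle genes lay highest at 0.62, and erythroid transcripts (-2.03) and MHC class II genes (-1.44) lowest.

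Transcripts of other cell types were measured beside these lists. Erythroid transcripts had a median log2 ratio of -2.03 over 4 members in macrophage-like cells. Hbb-bs had 125 CPM in the control and 0.720 CPM in the LOY library, Hba-a1 37.0 and 0.504 CPM, Hba-a2 871 and 3 UMIs, a ratio of 0.00771 (0.00159 to 0.0226), and Hbb-bt 763 and 0 UMIs, at least 114-fold lower against 3 counts. With Hbb-bt at that limit the median was again -2.03. In the Lyve1 cluster the 4 log2 ratios lay between -0.19 for Hbb-bs and -0.046 for Hba-a2. The added 10 CPM keeps the log2 ratio of low genes near 0, so these values do not show a smaller fold in that cluster. Summed erythroid levels in the control library were 216 CPM in macrophage-like and 273 CPM in B cell-like cells. They were 1.55 CPM in cluster 0, 1.95 CPM in monocyte-like and 3.85 CPM in neutrophil-like cells. Cardiomyocyte transcripts had a median of -0.54 over 7 members, with Tnnt2 at 14.9 and 29.6 CPM, Ttn at 15.1 and 16.2 CPM, Myl2 at 30.7 and 12.5 CPM and Mb at 13.4 and 4.75 CPM, and a median of 0.16 in the Lyve1 cluster and 0.15 with each library clustered on its own. Of fibroblast transcripts, Gsn alone was measured (134 and 118 CPM). No endothelial or platelet transcript reached 10 CPM, and their summed levels were 22.7 and 14.3 CPM for the former and 5.37 and 4.11 CPM for the latter.

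In monocyte-like cells (249 control and 233 LOY cells), the type I interferon list had a median log2 ratio of 0.57 over 22 members (0.42 to 0.69), 10 of them over 1.5-fold higher. The antiviral gene Rsad2 was at 22.7 and 111 CPM and the chemokine gene Cxcl10 at 38.9 and 148 CPM. The calprotectin genes S100a9 (17.5 and 225 CPM) and S100a8 (23.4 and 191 CPM) and the retinol enzyme gene Dhrs3 (18.2 and 77.2 CPM) were also among the 5 highest. Cebpb (2289 and 426 CPM), H2-M3 (55.8 and 6.43 CPM), the actin-binding gene Pfn1 (1453 and 389 CPM), Klf2 (1087 and 306 CPM) and the monocyte gene Plac8 (3728 and 1066 CPM), itself a leading gene of this cluster, were lowest. The profibrotic list had a median of 0.16 over 20 members, 5 over 1.5-fold higher and 5 lower. With each library clustered on its own the interferon and profibrotic medians were -0.73 and -0.63, of the other sign, and the profibrotic median was -0.32 at a minimum of 1000 UMIs, -0.016 at no more than 5% mitochondrial UMIs, -0.34 with doublets kept and -0.14 at resolution 0.5. The MHC class I list had a median of -0.68 and the dissociation and stress list -0.30 (-0.48 at a minimum of 1000 UMIs). In the separate clustering S100a9, S100a8, Rsad2 and Cxcl10 had log2 ratios of -2.33, -2.18, -0.91 and -1.06, so their direction depends on which cells are counted as monocyte-like. At a minimum of 1000 UMIs S100a9 and S100a8 had -0.023 and -0.41 and the MHC class I median was 0.022, and S100a9 had -0.24 at no more than 5% mitochondrial UMIs.

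In neutrophil-like cells (298 control and 122 LOY cells), the lowest genes were Camp, Ngp, Ltf, Serpinb1a and Cxcl10. Camp (cathelicidin) had 2880 and 0 UMIs, at least 148-fold lower against a limit of 3 counts in that class. Ngp had 1272 and 2 UMIs, a ratio of 0.0102 (0.00123 to 0.0369), and Ltf (lactoferrin) 434 and 2 UMIs, a ratio of 0.0299 (0.00360 to 0.109). Serpinb1a had 80 and 0 UMIs, at least 4.12-fold lower, and Cxcl10 305 and 1 UMIs, a ratio of 0.0212 (0.000536 to 0.119). The highest were Apoc2 (57.8 and 199.6 CPM), Clec4n (88.6 and 283 CPM), Mif (53.9 and 175 CPM), Puf60 (57.8 and 183 CPM) and Prdm2 (70.6 and 216 CPM). The granulocyte activation and maturation list had a median of -0.28 over 24 members (-0.21 with its 3 members at 0 UMIs set to 3 counts), 10 over 1.5-fold lower, 11 within 1.5-fold and 3 higher, among the latter the chemokine gene Ccl3 (469.8 and 1015 CPM) and Retnlg (5532 and 9257 CPM), also a leading gene of the cluster. The dissociation and stress list had a median of -0.46 over 24 members. The LOY sum was 120237 UMIs, so 1 UMI stood for 8.32 CPM.

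In B cell-like cells (813 control and 237 LOY cells), the histone genes Hist1h3e (20.3 and 92.2 CPM) and Hist1h4d (36.1 and 138 CPM), the galectin Lgals1 (43.3 and 148 CPM) and Mrps6 (45.5 and 143 CPM) were highest, together with Setbp1, at a ratio of 3.61 (1.95 to 6.40). Selenop, abundant in macrophages, had 237 and 3 UMIs, a ratio of 0.107 (0.0218 to 0.315), but with each library clustered on its own its log2 ratio was 0.29, of the other sign. Sap18 had 133 and 2 UMIs, a ratio of 0.127 (0.0152 to 0.466), Tmem163 128 and 2 UMIs, a ratio of 0.132 (0.0158 to 0.485), Cebpb 199 and 32.3 CPM, and Pfn1 1048 and 239.7 CPM. Naive lymphocyte genes had a median of -0.41 over 7 members, with the homing receptor Ccr7 at 716 and 281 CPM. T cell activation and inhibitory receptors had a median of -0.29 over 3 members (-0.79 to 0.10), and 2 cytotoxic lymphocyte genes were measured, too few for a median. The interferon list had a median of 0.58 over 14 members, but -0.12 with doublets kept, the oxidative phosphorylation list 0.28 over 27 and the dissociation and stress list -0.75 over 24. T cell-like and NK cell-like cells had too few LOY cells (97 and 47) for a comparison of expression.

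Cluster 0 had Chil3 at 1 and 53 UMIs, a ratio of 187 (32.1 to 7523), Ly6c2 at 21.2 and 183 CPM, Ccl5 at 334 and 1978 CPM, the fatty acid binding protein gene Fabp5 at 224 and 954 CPM and Ifitm1 at 198 and 768 CPM as its highest genes. The lysozyme gene Lyz1 (335 and 21.9 CPM), Retnla (5149 and 598 CPM), Klf2 (536 and 62.2 CPM), S100a9 (121 and 0 UMIs, at least 11.4-fold lower) and Bcl2a1d (169 and 20.1 CPM) were lowest. Retnla and Ifitm1 are also among the 10 leading genes of this cluster. The dissociation and stress list had here a median of -0.84 over 25 members, 18 of them over 1.5-fold lower. The median was -0.56 over 21 members for the profibrotic list, -1.40 over 16 for the resident list, -1.16 over 15 for the efferocytosis and complement list, -0.68 over 22 for the lysosome list and -0.67 over 25 for the inflammatory list. The recruited monocyte list had a median of 0.50 over 14 members. With a pseudocount of 50 CPM the resident, efferocytosis and complement, lysosome and recruited monocyte medians were -0.81, -0.73, -0.35 and 0.23.

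Whether LOY-library cells without a Y-linked UMI differed from those with one was asked in macrophage-like cells at 1000 UMIs. The LOY library had 3654 cells without and 47 with such a UMI, and the control library, where the split is background, 4183 and 469. The median log2 ratio of profibrotic genes, cells without over cells with, was -0.15 in the LOY library (-0.28 to 0.23) and 0.069 in the control (-0.014 to 0.11), a difference not detectable at this depth. At 500 UMIs the LOY median was 0.51 and at 2000 UMIs 0.027, both of the other sign. Tgfb1 had 262 and 404 CPM in the LOY library, a ratio of 0.649 (0.413 to 1.08), and 207 and 205 CPM in the control. In this split 3 lists had a LOY interval wholly above 0. X-linked partners had 0.32 (0.033 to 1.55), MHC class I genes 0.26 (0.0013 to 0.59) and hypoxia and glycolysis genes 0.18 (0.059 to 1.28). Their control medians were 0.16, 0.060 and -0.018. In the control split the intervals of 3 lists left out 0 as well, those of interferon response (0.19), MHC class II (0.13) and resident macrophage genes (-0.10). The 5 highest genes, Zfp106, Tcirg1, Hadha, Mbd3 and Pdcd10, had 106 to 117 CPM in cells without and 0 UMIs in the 47 cells with a Y-linked UMI, where 0 UMIs allow up to 63.8 CPM. The 5 lowest, Gosr2, Ednrb, Brwd3, Pwp1 and Impad1, rested on 4 to 8 UMIs in those cells.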

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

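The tests on B cell-like neighbours and on GC content for the higher and the lower genes apart were chosen after the result was seen, and the other tests before. All concern 2 libraries with 1 per group, so any difference in preparation or sequencing stands with the marrow genotype.

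Gm47283, a gene model on chromosome Y (mm10, 90784738 to 90816464) outside the Y-linked list, stood out because it was not lower in the LOY library. It had 25.3 CPM in the control (1045 UMIs) and 32.8 CPM in the LOY library (574 UMIs), 129.8% of the control level (117% to 144%). Gm21860, at 90754513 to 90754821 and named after its values were seen, was lower there, with 7.02 CPM in the control (6.24 to 7.88) and 3.32 CPM in the LOY library (2.52 to 4.29). Whether the UMIs of these gene models come from chromosome Y alone was not tested, so they are not read as a retained Y chromosome.

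The cell cycle list went opposite ways in 2 classes, with a median log2 ratio of 0.62 in macrophage-like cells and -1.27 in neutrophil-like cells. The difference between the classes was not tested. Of the 17 members measured in neutrophil-like cells, 8 had 0 UMIs in a library, and with these set to 3 counts the median was -0.080, so depth limits the neutrophil-like value, which was -0.36 with equal cell weights. The median was also below 0 in B cell-like cells (-0.47, interval -0.78 to -0.21), where no measured member had 0 UMIs, and was -0.18 in monocyte-like cells (-0.42 to 0.10) and 0.22 in cluster 0 (0.062 to 0.43).

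The first pattern weighed was the partial separation of macrophage-like cells by library. Clusters with over 90% of their cells from the own library held 38.1% of control and 60.4% of LOY macrophage-like cells. With equal cell numbers, 90.2% of a macrophage-like cell's 15 nearest neighbours came from its own library, against 50.2% with shuffled labels. The tables argue against a depth gap as the whole cause, since 86.9% remained after every cell was thinned to 1000 UMIs. The same holds for the dissociation response, since 87.5% remained without the stress list and the 200 genes that go most with it. With both steps together 84.4% remained. Whether either contributes in part was not tested. A difference that also sets other cell types apart stays open, because B cell-like cells thinned to 500 UMIs had 62.2% of neighbours from their own library, between the bounds of 60% and 80%, against 72.4% for as many macrophage-like cells at that depth. The marrow genotype, the biological explanation the design gives, also stays open and was not tested apart from the library.

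The second pattern was a set of genes at least 1.5-fold apart the same way in all 5 classes compared. Of 1205 genes with enough counts in each, 42 were lower in the LOY library, led by Cebpb, Pfn1, Btg2, Klf2 and Nr4a1, and 19 were higher, led by Cd52, Ifi35, H2afj, Uqcrq and Actb. The tables argue against reads shared with near-identical genes, since 9.52% of the lower genes (4 of 42, Ubb, Eno1, Bcl2a1b and Ppia) share at least 50% of the 31-base words in their last 500 bases with another gene, against 3.06% of the other genes compared. Removing the trend with GC content left 63.9% of all these genes past 1.5-fold and 76.2% of the lower ones (32 of 42), between the bounds of 50% and 80%, so that GC content stays open for them, although their median GC of 43.9% was near the 42.6% of the other genes compared. It left 36.8% of the higher genes (7 of 19, median GC 51.2%), under the bound of 50% set for a GC-linked difference. However, genes such as Cox4i1 and Ifi27l2a, with smallest log2 ratios of 0.59 and 0.62, passed 1.5-fold narrowly. Lower genes such as Ube2n and Ewsr1, with smallest absolute log2 ratios of 0.59 and 0.60, passed as narrowly. The outcome for the higher genes is the one set for GC content, but a small correction can drop genes that pass narrowly. It therefore does not settle GC content as their cause. Of the lower genes, Btg2, Klf2, Nr4a1, Zfp36 and Klf6 belong to the dissociation and stress list. The median of that list was below 0 in all 5 classes, from -1.28 in macrophage-like to -0.30 in monocyte-like cells. Whether the dissociation response accounts for part of this pattern was not tested. An effect of genotype in all lineages was not tested either.

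The third pattern was the Y-linked signal that remains in the LOY library. Free RNA from cells with the Y chromosome would spread the 245 UMIs over cells by depth, and 1000 such draws gave 3 to 13 cells with at least 2 of them (95% range, median 7). The library had 39, which argues against free RNA as the whole source, and a minority of cells that carry the Y chromosome may be present. In the control library the same draws gave 1190 to 1260 cells, and 1210 were seen. Where such cells come from was not tested.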

How the results depend on the processing

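Alternatives other than the Lyve1 cluster, thinned cells and the class without cycling clusters, which were chosen after seeing the data, were chosen before the data were examined. The 5 list medians followed here as main results were picked after the data were seen. The cause was not tested for the moves below, unless the setting itself gives it. The Y-linked level in the LOY library stayed between 9.08% (Eif2s3y alone) and 13.3% (Ddx3y alone) of the control. The share of cells with a Y-linked UMI follows depth and gene number by construction. In the control it was 6.42% at 500 UMIs, 21.9% at 2000, and 5.11%, 4.88%, 1.39% and 1.11% with Ddx3y, Eif2s3y, Kdm5d and Uty alone. In the LOY library it was 0.618%, 2.03%, 0.605%, 0.585%, 0.0418% and 0.125% in that order. The estimated share without Y transcripts moved past its counting interval only with Kdm5d alone, to 97.0% overall and 95.7% in macrophage-like cells.

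The macrophage-like share moved in control and LOY to 52.9% and 79.96% at a minimum of 1000 UMIs, 71.3% and 74.5% at no more than 5% mitochondrial UMIs, 48.6% and 56.7% with doublets kept, 55.1% and 70.5% at resolution 2, and 66.7% and 54.1% with separate clustering. At resolution 0.5 the LOY share was 79.0%. The B cell-like share was 5.24% and 3.64% at no more than 5% mitochondrial UMIs, and 1.29% in the LOY library at a minimum of 1000 UMIs.

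In macrophage-like cells the 5 list medians kept their sign under every alternative run. The profibrotic median was 0.34 at 1000 UMIs, 0.21 with a pseudocount of 50 CPM, 0.19 with monocyte-like cells added and 0.33 in the Lyve1 cluster. The median of TGF-β ligands, activation and receptors was 0.23 with CPM free of mitochondrial and ribosomal-protein genes and 0.016 in the Lyve1 cluster. The MHC class II median was -1.61 at the 5% mitochondrial limit, -1.59 with doublets kept, -1.32 at resolution 0.5, -1.999 with separate clustering, -1.32 with equal cell weights, -1.68 and -1.25 with pseudocounts of 1 and 50 CPM, -1.37 with monocyte-like cells added, -1.97 in the Lyve1 cluster and -1.37 with thinned cells. The cell cycle median was 0.73 with separate clustering, 0.81 and 0.33 with pseudocounts of 1 and 50 CPM, 0.39 in the Lyve1 cluster and 0.33 without cycling clusters. The dissociation and stress median was -0.84 at 1000 UMIs, -1.37 with doublets kept, -1.06 at resolution 2, -1.18 with separate clustering, -1.18 with equal weights, -1.32 and -1.01 with pseudocounts of 1 and 50 CPM, -0.75 in the Lyve1 cluster, -1.19 with thinned cells and -1.21 without cycling clusters. Tgfb1 had a log2 ratio of 0.48 in the Lyve1 cluster and stayed within its counting interval under the other alternatives. The profibrotic median of the split by Y-linked UMI was 0.51 at 500 UMIs and 0.027 at 2000 UMIs, both of the other sign.

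Among log2 ratios and medians that lay at 1.5-fold or further, these turned sign. In monocyte-like cells S100a9 had -0.023 at 1000 UMIs, -0.24 at the 5% mitochondrial limit and -2.33 with separate clustering, S100a8 -0.41 at 1000 UMIs and -2.18 with separate clustering, and Rsad2 -0.91 and Cxcl10 -1.06 with separate clustering, while the MHC class I median was 0.022 at 1000 UMIs. Selenop in B cell-like cells had 0.29 with separate clustering, and Pmaip1 in macrophage-like cells 0.010 in the Lyve1 cluster. Of the 1701 alternative values of named genes, 1110 stayed within their counting interval, 582 moved past it and 9 are the turns from 1.5-fold or further given above. Of those that moved, the signs of 4 smaller ratios of macrophage-like cells turned, Ddx3x (0.0062) and Ctss (-0.18) in the Lyve1 cluster, Cenpa (0.14) with separate clustering and Hsp90ab1 (-0.0039) with thinned cells. Of 846 alternative values of list medians over all classes, 49 had the other sign, among them these. In macrophage-like cells the Lyve1 cluster turned the inflammatory (0.13), resident (0.10), cardiomyocyte (0.16) and X-linked partner (0.065) medians, separate clustering the cardiomyocyte median (0.15), and 6 alternatives the median of TGF-β signalling and target genes, which was 0.0029. Monocyte-like medians turned with separate clustering for interferon (-0.73), inflammatory (-0.83) and profibrotic genes (-0.63), and B cell-like interferon genes with doublets kept (-0.12). Other macrophage-like medians moved past their interval by over 1.5 times. With a pseudocount of 50 CPM, which shrinks ratios of low genes, MHC class I had -0.54, hypoxia and glycolysis 0.21 and erythroid transcripts -0.71 (-4.67 with 1 CPM). At 1000 UMIs inflammatory genes had -0.15, resident genes -0.52 and recruited monocyte genes 0.73, and the last 0.21 with monocyte-like cells added. Efferocytosis and complement genes ran from -0.24 at resolution 2 to -0.0062 with equal weights, and p53 genes had -0.20 with thinned cells. The median of all measured macrophage-like genes, judged against a band of 0.1 either way, lay between -0.039 and -0.0012. Of the 20 genes named there, 7 to 19 were named again, the fewest in the Lyve1 cluster. No paired analysis was possible because each group is 1 library. Depth limits the LOY neutrophil-like and B cell-like classes, with medians of 819 and 854 UMIs per cell.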

Other observations

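In the monocyte-like class the resident macrophage list had a median log2 ratio of 0.36 over 11 members (0.15 to 0.60), at the percentile 99.5 of random lists, with 4 over 1.5-fold higher and 0 lower. C1qa, C1qb and Apoe, which are abundant in macrophages, were higher as well, C1qa at 260.3 and 708 CPM, C1qb at 326 and 860.3 CPM and Apoe at 4677 and 9223 CPM, and the efferocytosis and complement list had a median of 0.25 over 14 members (0.10 to 0.45). With each library clustered on its own the 2 medians were 0.0092 and -0.0092, and the first was 0.033 with doublets kept, so these medians depend on which cells are counted as monocyte-like. Hypoxia and glycolysis genes had a median of 0.38 over 21 members, with the glycolytic enzyme Pkm at 583 and 1195 CPM, but a median of 0.068 at no more than 5% mitochondrial UMIs. The cytokine Il1b was lower, at 2048 and 1032 CPM.

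Neutrophil-like cells of the LOY library had lower MHC class II genes, with a median log2 ratio of -1.14 over 8 members, and -0.34 with doublets kept and -0.35 with separate clustering. H2-Eb1, which is abundant in control macrophage-like cells, had 1243 and 183 CPM there. The median was -0.15 in B cell-like cells (-0.28 to 0.042), with 0 of 11 members over 1.5-fold lower, and -0.12 in monocyte-like cells (-0.21 to -0.040), where it was 0.35 at a minimum of 1000 UMIs, 0.32 at no more than 5% mitochondrial UMIs and 0.24 with doublets kept. In cluster 0 the MHC class II median was -0.16 over 11 members, and H2-Oa (52.9 and 170.0 CPM) and H2-DMb2 (88.6 and 190.1 CPM) were higher while H2-Aa (10546 and 6519 CPM) and H2-Eb1 (11289 and 6978 CPM) were lower. Haemoglobin transcripts were lower in B cell-like cells as in macrophage-like cells. Hbb-bs had 179 and 0 UMIs, at least 7.09-fold lower against 3 counts, and Hba-a1 159 and 0 UMIs, at least 6.30-fold lower.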
